A study of Mus musculus with 6 samples.

How the data were processed

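Poly(A) RNA was sequenced from 6 libraries of a doxycycline-inducible mouse embryonic fibroblast line, 2 each for siControl, siJunb and siH1f0. Groups and replicate numbers come from the sample labels. The labels give day 1 after induction and the series description day 3 with a sort for GFP-positive cells; the groups are the same under both. The deposited values are raw read counts per gene symbol, whole numbers that were not normalised. The submitters' processing notes name HISAT2, Subread, featureCounts and the build mm10, without versions. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Coordinates come from the GRCm38.p6 gene table. Of 24516 symbols, 23591 were found in it. All 6 library columns were used, and the gene length column was not used here.

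Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM scaling gave factors from 0.979 to 1.02, and the filterByExpr filter left 13427 genes. The quasi-likelihood F test was fitted to all 6 libraries with group as the only term, which leaves 3 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 4263 genes for siJunb, 3060 for siH1f0 and 5163 for the direct comparison. An exact permutation of 2 libraries against 2 cannot go below p = 0.333 (two-sided), so calls on single genes rest on the spread shared across genes. CPM are counts scaled to the library total, computed from the deposited counts. Errors are SDs over libraries or SEs of the log2 fold change. Library totals ran from 48690447 to 85979630 counts, with a median of 1484 to 2682 counts per tested gene. The spread between replicates exceeded counting noise in each group (chi-square per degree of freedom 74.6, 3.80 and 3.85 for siControl, siJunb and siH1f0).

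The method was tested on simulated data with known changes. For siJunb (13295 genes) it recovered 32.8% of 67 genes changed 1.25-fold, 64.2% of 67 changed 1.5-fold and 80.3% of 66 changed 2-fold, with 9 false calls among 127. For siH1f0 (13285 genes) the shares were 29.9%, 77.6% and 87.9%, with 13 false calls among 143. A list shifted by -0.4 on the log2 scale in the siJunb simulation was called by camera, and 0 other lists were. Genes were simulated independently, so this does not test false calls of lists whose members vary together. In the data the correlation estimated for siJunb was 0.829 for linker histones and 0.745 for oxidative phosphorylation.

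The design, the rule for named genes, the 29 gene lists and, with the exceptions given below, the alternatives were fixed before the data were examined. The rule names Junb, H1f0, Mef2c, Gata4 and Tbx5 in every comparison. It adds the 6 higher and 6 lower called genes with the largest log2 change per knockdown, and 4 and 4 for the direct comparison. These needed a mean of at least 5 CPM and groups whose libraries did not overlap, and symbols of the Gm, Rik and bare Ensembl kind were left out. It then adds up to 3 called members per list with the smallest p, or 4 for the cardiac, fibroblast and matrix, AP-1 family, AP-1 target and linker histone lists. For a cardiac list with no called member it takes the 2 members with the highest CPM. Some genes that met the rule are not reported here.

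The lists were reprogramming factors, cardiac sarcomere, cardiac calcium and conduction, cardiac transcription factors, fibroblast and extracellular matrix, myofibroblast and TGF-beta response, AP-1 family, AP-1 target genes, linker histones, core histone clusters, G2/M cell cycle, S phase, p53 response and cell cycle arrest, senescence-associated secretion, interferon-stimulated genes, NF-kB and inflammation, skeletal muscle, smooth muscle, neuronal, endothelial, epithelial, macrophage and leukocyte, adipocyte, cartilage and bone, pluripotency, oxidative phosphorylation, integrated stress response, cholesterol synthesis, and chromatin barriers to reprogramming. The 25 lists with at least 5 measured members were tested with camera (limma 3.58.1, voom weights, preset correlation 0.01), adjusted per comparison. Camera called 8 lists for siJunb, 7 for siH1f0 and 6 for the direct comparison. With a correlation estimated per list 0 were called in each. Rotation tests (fry), which do not compare a list with other genes, called 9, 9 and 15.

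The alternatives were RLE size factors, total counts only, no count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, only the 4 libraries compared, the replicate number as a block, and each library left out in turn. When a library is left out, the other library of its group is assumed to vary like the other groups. Counts without genes that hold a chosen heptamer were added after seeing the data. So was a camera test of the sarcomere list without its 4 members that hold a siJunb heptamer. Unchanged groups, siControl included, were simulated 20 times from a mean and dispersion per gene common to all groups, to gauge the overlap of calls.

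Heptamers were searched in the 3' UTRs of GENCODE vM21 (GRCm38) with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. The scan covered 9972 genes with a mean of at least 4 CPM and a 3' UTR of at least 30 bases, and left out Junb and H1f0. Log2 fold changes, limited to 1 either way, were compared between genes with and without each heptamer. Of 16384 heptamers, 16060 lay in at least 50 genes, and those with z under -7 were chosen (under -5 in replicate 1 alone). Matched shares come from 1000 draws. Several settings were made after values had been seen. They are the z limits, leaving out the targets, the control matched on GC content, the 200 matched genes per sarcomere gene and a tighter exclusion of rearranged heptamers that overlap a chosen one. That exclusion moved GCGGAAC from 48.1% to 43.4% and left GAGCGCT at 57.0%. The siRNA sequences are not given in the sources used here.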

Results

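Gene expression was measured by poly(A)-selected RNA sequencing in a line of mouse embryonic fibroblasts in which doxycycline (1 ug/mL) switches on Mef2c, Gata4 and Tbx5, a trio of transcription factors used to turn fibroblasts into cardiomyocyte-like cells. The line carries an eGFP reporter named for Myh6, the gene of the cardiac alpha-myosin heavy chain. Cells were transfected on the day before induction with a control siRNA (siControl), an siRNA against Junb, which encodes a subunit of the AP-1 transcription factor (siJunb), or an siRNA against H1f0, which encodes linker histone H1.0 (siH1f0). Each of the 3 groups held 2 libraries, described as biological replicates. The sample labels give harvest at day 1 after induction, whereas the series description gives day 3 and a sort for GFP-positive cells; which of the descriptions holds for these libraries was left open. The libraries held 85979630 and 65998575 counts for siControl, 63888652 and 48690447 for siJunb, and 59380780 and 65746378 for siH1f0. In all, 13427 genes entered the tests. The siControl libraries differed from each other far beyond counting noise (chi-square per degree of freedom 74.6), more than the siJunb pair (3.80) or the siH1f0 pair (3.85). That measure gives most weight to abundant RNAs such as Rn45s, at 1.90% of counts in siControl 1 and 0.627% in siControl 2. Over genes weighted alike the pairs were similar, with SDs of the log2 ratio of 0.312 in siControl, 0.317 in siJunb and 0.284 in siH1f0. The first principal component (41.0% of the variance) separated the 3 groups and the second (23.6%) separated siControl from both knockdowns, with siControl 1 at its end.

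The siRNA targets were examined first in every library. Junb was at 39.1 and 35.7 CPM in siControl, 10.7 and 8.90 CPM in siJunb, and 29.98 and 31.1 CPM in siH1f0. It fell from 37.4 ± 2.40 CPM in siControl to 9.79 ± 1.26 CPM in siJunb (SD, n = 2 each), a log2 change of -1.93 ± 0.09 (SE; edgeR adjusted p = 1.6e-05). H1f0 was at 798 and 743 CPM in siControl, 666 and 651 CPM in siJunb, and 51.6 and 54.4 CPM in siH1f0. It fell from 770 ± 39.5 CPM to 53.04 ± 2.00 CPM in siH1f0 (SD, n = 2 each), a log2 change of -3.86 ± 0.06 (SE; adjusted p = 7.12e-09). H1f0 also fell in siJunb, by 0.23 on the log2 scale (adjusted p = 0.021), a call lost with only the 4 libraries compared (adjusted p = 0.0616) and without either siJunb or either siH1f0 library (up to 0.198). Junb differed from siControl by -0.29 in siH1f0, which did not pass the test (adjusted p = 0.0778). That difference passed with DESeq2 (0.0427), with no count filter (0.00233), without siControl 1 (-0.22, 0.0179) and without siControl 2 (-0.36, 1.97e-05). In the GRCm38.p6 annotation Junb (gene 16477) is a protein-coding gene on chromosome 8 from 84976909 to 84978748. H1f0 (gene 14958) lies on chromosome 15 from 79028212 to 79030504.

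None of the induced factors passed edgeR's test on the filtered counts of all 6 libraries. Mef2c (chromosome 13, 83504017 to 83667079) was at 531 ± 252 CPM in siControl, 741 ± 16.2 CPM in siJunb and 753 ± 55.4 CPM in siH1f0 (SD, n = 2 each). Gata4 (chromosome 14, 63198914 to 63271712) was at 1127 ± 401, 1367 ± 33.8 and 1436 ± 61.8 CPM, and Tbx5 (chromosome 5, 119796514 to 119885220) at 2206 ± 492, 2409 ± 26.7 and 2552 ± 95.8 CPM, in the same order. The log2 differences from siControl were 0.48, 0.28 and 0.13 in siJunb (adjusted p = 0.217, 0.333 and 0.502) and 0.50, 0.35 and 0.21 in siH1f0 (adjusted p = 0.267, 0.299 and 0.334). Between the knockdowns they were 0.02, 0.07 and 0.08 (adjusted p = 0.957, 0.812 and 0.648). The siControl libraries stood apart from each other for all 3 factors, with Mef2c at 354 and 709 CPM, Gata4 at 844 and 1411 CPM and Tbx5 at 1858 and 2554 CPM. Without siControl 1 the differences of Gata4 and Tbx5 in siJunb became -0.045 and -0.084, the latter past the test (adjusted p = 0.0159). Without siControl 2 all 3 factors passed as higher in both knockdowns, Mef2c by 1.06 in siJunb and 1.09 in siH1f0. With no count filter all 3 also passed as higher in both, with Mef2c at adjusted p = 7.04e-18 and 6.66e-20, Gata4 at 6.24e-07 and 8.51e-11, and Tbx5 at 0.0469 and 1.72e-04. Between the knockdowns Gata4 and Tbx5 passed as higher in siH1f0 with only the 4 libraries compared (0.0133 and 0.00222) and without either siControl library (up to 0.0156 and 0.00222). Counts from the induced copies and from the cells' own genes cannot be separated in these values. Mef2c holds in its 3' UTR a heptamer over-represented among genes lower in siH1f0.

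**Figure D1:**
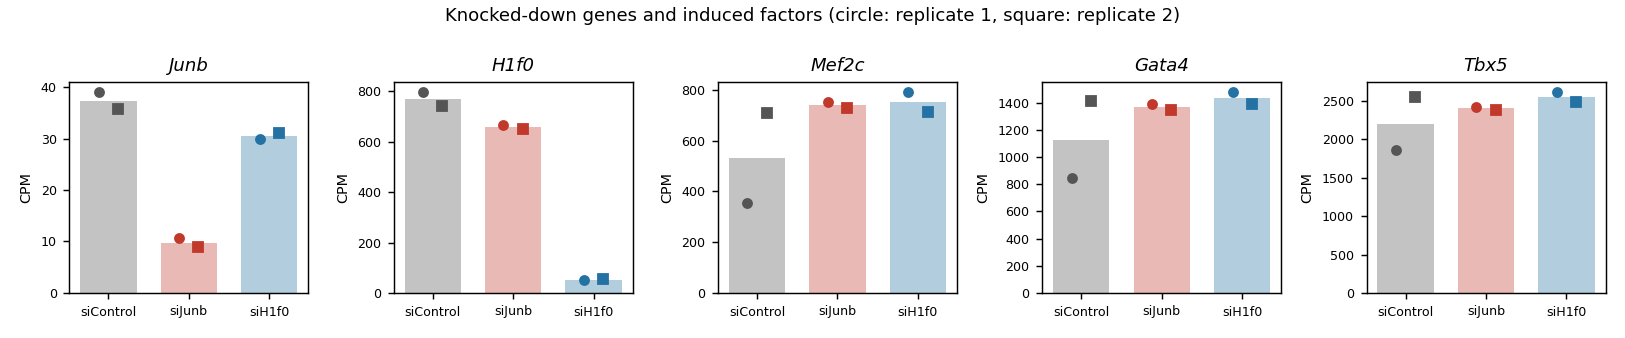
CPM (y axis, from 0) of the siRNA targets Junb and H1f0 and of the induced factors Mef2c, Gata4 and Tbx5 in each library of the 3 groups, with bars for group means and a circle for replicate 1 and a square for replicate 2. Junb is lowest in siJunb (9.79 CPM) and H1f0 in siH1f0 (53.04 CPM), while siControl 1 lies below siControl 2 for the induced factors.

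The comparison of siJunb with siControl asks which genes depend on Junb early after induction. Several cardiac muscle genes were lower in siJunb. Actc1, the cardiac alpha-actin gene, fell from 20.9 ± 1.78 to 3.90 ± 0.163 CPM (SD, n = 2 each), a log2 change of -2.43 ± 0.10 (SE; adjusted p = 7.86e-06). Myl7, the atrial myosin light chain, fell by 1.63 (adjusted p = 9.28e-05). Genes of the matrix and of inflammation were higher: C3, complement component 3, rose from 13.9 ± 0.326 to 50.1 ± 1.00 CPM (log2 1.85 ± 0.08, adjusted p = 1.02e-05). Dcn, which encodes the matrix proteoglycan decorin, rose from 4.74 ± 0.666 to 15.3 ± 0.306 CPM (log2 1.68 ± 0.11). The other genes with the largest increases were Peg10, an imprinted retrotransposon-derived gene (1.28), Col8a1, a collagen chain (1.23), Lrp4, a membrane receptor gene (1.19), and Ccnd1, cyclin D1 (1.09). The other genes with the largest decreases were Rxfp1, the relaxin receptor (-2.12), Rmrp, the RNA of RNase MRP (-1.83), and Cdsn, corneodesmosin (-1.56). Rmrp was at 26.0 CPM in siControl 1 and 6.65 CPM in siControl 2 against 5.80 and 3.35 CPM in siJunb. In all, edgeR called 2209 of 13427 genes, 1159 higher and 1050 lower, of which 111 and 254 changed at least 1.5-fold. The libraries of the groups did not overlap for 58.0% of genes, against 33.3% by chance. The number of calls was 4605 without siControl 1, 5521 without siControl 2, 371 without siJunb 1, 352 without siJunb 2, 1103 without siH1f0 1 and 1115 without siH1f0 2, and 1094 with only the 4 libraries compared. Without a scaling factor beyond total counts, the calls were 884 higher and 1369 lower. Of 66 called genes named by rule, 29 passed without each of the 6 libraries in turn, among them all those of this paragraph except Rmrp. That gene lost its call without either siJunb or either siH1f0 library (adjusted p up to 0.268).

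The fixed list of cardiac sarcomere genes was lower in siJunb: of 21 measured members 8 fell and 1 rose (11 and 1 adjusted over the list alone), with a median log2 change of -0.36 (camera adjusted p = 2.78e-04; adjusted p = 0.553 with an estimated correlation). Besides Actc1 and Myl7, the members that fell were Tnni3, cardiac troponin I (-0.92), Lmod2, which acts at thin-filament ends (-0.73), Xirp1 (-1.54), Myoz2 (-0.58), Ldb3 (-0.42) and Tnnc1 (-0.32), and the member that rose was Mybpc3 (0.41). The fibroblast and extracellular matrix list was higher, with 8 of 26 members up and 2 down (11 and 3 adjusted over the list alone; median 0.13, camera adjusted p = 0.0419; adjusted p = 0.553 with an estimated correlation). Examples were Dcn, Tnc, the gene of tenascin-C (0.63), and Col5a2 (0.28), and the members that fell were Loxl1 (-0.41) and Fbln1 (-0.72). That list lost its call without siControl 1 (adjusted p = 0.208), siJunb 1 (0.111), siH1f0 1 (0.0549) or siH1f0 2 (0.0551). In the p53 response list 9 of 19 members rose and 2 fell (10 and 3 adjusted over the list alone; median 0.20, camera adjusted p = 0.00266; adjusted p = 0.553 with an estimated correlation). Ccng1, cyclin G1, rose by 0.58 and Zmat3, an RNA-binding protein gene induced by p53, by 0.47, while Plk2 (-0.34) and Sesn1 (-0.25) fell. The NF-kB and inflammation list had 5 of 14 members up and 0 down (5 and 0 adjusted over the list alone; median 0.12, camera adjusted p = 0.0183; adjusted p = 0.553 with an estimated correlation): C3, the adhesion molecule gene Vcam1 (0.99), the serum amyloid gene Saa3 (0.53), Nfkb2 (0.24) and Nfkbiz (0.20). G2/M genes were lower, with 0 of 23 up and 5 down (0 and 6 adjusted over the list alone; median -0.12, camera adjusted p = 0.00209; adjusted p = 0.553 with an estimated correlation): Ube2c (-0.42), Ccnb2 (-0.30), Cenpf (-0.30), Aurkb (-0.26) and Top2a (-0.22). Without siJunb 1 or siJunb 2, Col5a2, Plk2, Ube2c, Ccnb2 and Aurkb lost their calls (adjusted p up to 0.128, 0.0563, 0.0696, 0.125 and 0.160), as did Loxl1 and Saa3 without siJunb 2 (0.0843 and 0.155). Ccng1, Saa3, Vcam1, Nfkb2, Ldb3 and Myoz2 hold in their 3' UTRs a heptamer over-represented among genes lower in siJunb. Among 851 searched genes lower in siJunb 33.1% hold one, against 18.3% of matched genes. The heptamers were chosen from these same fold changes, so a larger share among lower genes follows from the choice and is no separate evidence. Members named only to complete a count of 5 or fewer, here and in the other comparisons, were chosen after their values were seen, as were Xirp1, Myoz2, Ldb3 and Tnnc1.

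Linker and core histone genes were lower in siJunb. Of 7 measured linker histone genes 0 rose and 3 fell (0 and 6 adjusted over the list alone; median -0.65, camera adjusted p = 0.00209; adjusted p = 0.553 with an estimated correlation): Hist1h1c (-0.66), H1fx (-0.48) and H1f0 (-0.23). Of 36 measured core histone genes 0 rose and 6 fell (0 and 6 adjusted over the list alone; median -1.12, camera adjusted p = 2.21e-05; adjusted p = 0.553 with an estimated correlation), among them Hist1h3c (-3.08), Hist1h2ak (-2.78) and Hist1h2bc (-0.70). These core histone genes were near the limit of detection (median 0.215 CPM), and their counts summed to 47.3 CPM in siControl 1, 38.2 CPM in siControl 2, and 32.4 and 30.8 CPM in siJunb. Most histone mRNAs lack a poly(A) tail and come from near-identical gene copies, so these counts are uncertain. Without siControl 1 the core histone median was -0.52. H1fx, Hist1h2ak and Hist1h2bc lost their calls without either siJunb library, H1f0 without either siJunb or siH1f0 library, and Hist1h3c without any 1 library but siControl 2 (adjusted p up to 0.0921, 0.171, 0.132, 0.198 and 0.165). The oxidative phosphorylation list passed the test as higher (median 0.07, camera adjusted p = 0.0183; adjusted p = 0.859 with an estimated correlation), with 2 of 73 members up, Atp5b (0.22) and Sdha (0.18), and 0 down (0 and 0 adjusted over the list alone). Without siControl 2 its median was -0.03 and it did not pass (adjusted p = 0.363), and both genes lost their calls without either siJunb or either siH1f0 library (adjusted p up to 0.158 and 0.238).

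The other 17 lists tested did not pass in siJunb (camera adjusted p from 0.131 to 0.901). Among AP-1 target genes 4 of 18 rose and 3 fell (6 and 3 adjusted over the list alone), including Ccnd1, Hmga2 (0.89), Hbegf (-0.64) and Dusp1 (-0.47). Of 13 AP-1 family genes 3 rose and 3 fell (4 and 5 adjusted over the list alone): Mafk (0.31), Maf (0.26), Fosl2 (0.23), Junb, Jund (-0.46) and Atf3 (-0.21). Of 19 myofibroblast and TGF-beta genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), including Ltbp2 (0.64) and Acta2 (0.33). Among 12 calcium and conduction genes 2 rose and 1 fell (2 and 1 adjusted over the list alone): Nppb, the B-type natriuretic peptide gene (1.01), the potassium channel gene Kcnj2 (0.34) and Casq2, cardiac calsequestrin (-0.80). Of 9 cardiac transcription factor genes 2 rose, Hopx (0.50) and Mef2d (0.47), and 0 fell (2 and 0 adjusted over the list alone). Interferon-stimulated genes had 6 of 38 up and 1 down (6 and 1 adjusted over the list alone), with Stat2 (0.50), Usp18 (0.34) and Mx2 (-0.55), and genes of senescence-associated secretion 4 of 18 up and 2 down (5 and 3 adjusted over the list alone), with Ccl7 (0.88) and Csf1 (0.47). Counts up and down were 1 and 4 of 19 for cholesterol synthesis (1 and 5 adjusted over the list alone), with Insig1 (-0.46), Hmgcs1 (-0.32) and Dhcr7 (-0.31), and 2 and 3 of 23 for chromatin barriers (2 and 5), with Hmgb1 (-0.40), Ezh2 (-0.28) and Suz12 (-0.22). They were 0 and 2 of 23 for S phase (0 and 1 adjusted over the list alone), Ccne2 (-0.48) and E2f1 (-0.19), and 1 and 1 of 17 for the integrated stress response (1 and 1), Asns (0.18) and Ddit3 (-0.36). For markers of other cell types they were 1 and 0 of 9 for smooth muscle (1 and 1 adjusted over the list alone; Mcam 0.36), 0 and 1 of 6 for neuronal (0 and 1; Tubb3 -0.56), 1 and 0 of 6 for macrophage and leukocyte (1 and 0; Csf1r 1.39, at 0.641 against 0.240 CPM), and 0 for endothelial, adipocyte, and cartilage and bone genes (5, 5 and 6 measured). The median, the mean or the test differed in sign for cardiac transcription factors, smooth muscle, endothelial and chromatin barrier genes. Lists with fewer than 5 measured members were not tested: skeletal muscle (4 measured, 0 called), pluripotency (2 measured, Klf4 up by 0.20), the induced factors (3) and epithelial genes (0 measured). Of the genes in this paragraph, Mafk, Acta2, Nppb, Kcnj2, Hopx, Usp18, Hmgcs1, Ezh2, Ccne2, Ddit3 and Tubb3 lost their calls without either siJunb library (adjusted p up to 0.177). Maf, Dhcr7, Suz12, E2f1, Asns, Csf1r and Klf4 lost them also without either siH1f0 library (up to 0.269), Jund, Mx2 and Hmgb1 without siJunb 2 (0.0803, 0.105 and 0.0505) and Mcam without siJunb 1 (0.114). Ccne2, E2f1, Insig1, Maf, Stat2 and Suz12 hold a 3' UTR heptamer over-represented among genes lower in siJunb.

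**Figure D2:**
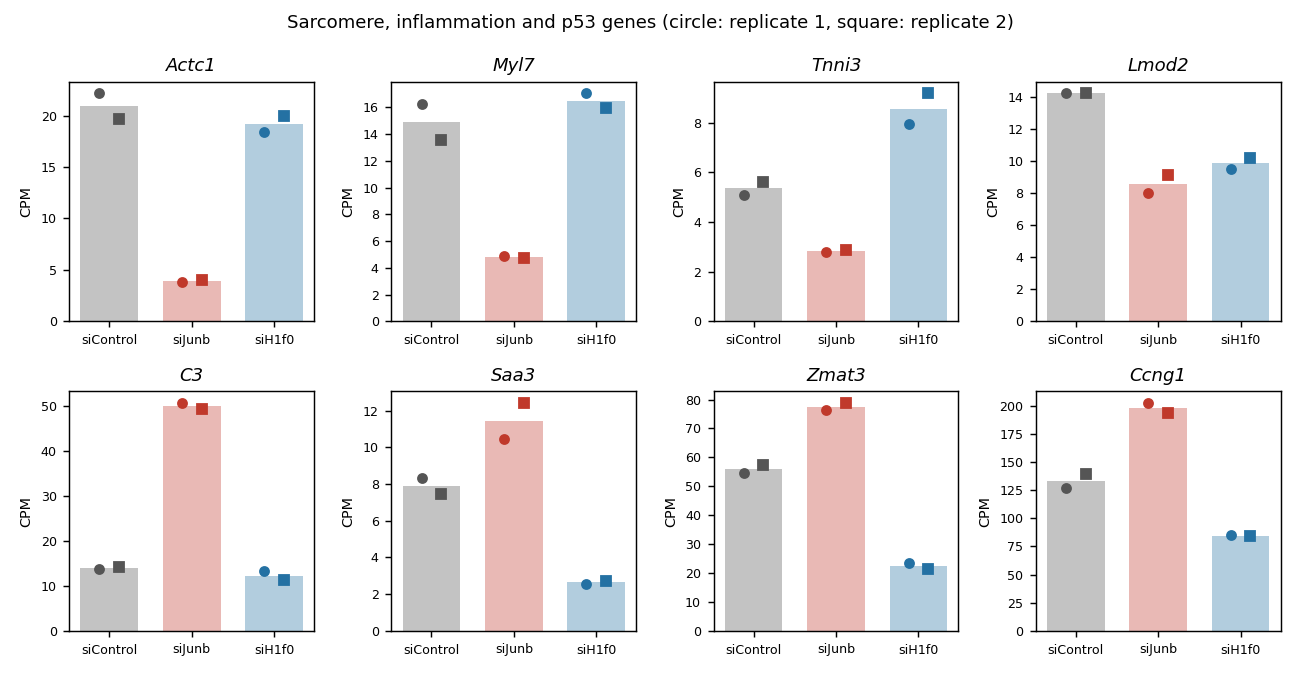
CPM (y axis, from 0) in each library for the sarcomere genes Actc1, Myl7, Tnni3 and Lmod2, the inflammation genes C3 and Saa3, and the p53-response genes Zmat3 and Ccng1, with bars for group means and a circle for replicate 1 and a square for replicate 2. Actc1 lies near 3.90 CPM in siJunb against 20.9 in siControl and 19.2 in siH1f0, and Zmat3 near 22.5 CPM in siH1f0 against 55.9 in siControl and 77.6 in siJunb.

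The comparison of siH1f0 with siControl asks the same of linker histone H1.0. Apart from H1f0 itself, Zmat3 fell from 55.9 ± 1.80 to 22.5 ± 1.39 CPM (SD, n = 2 each), a log2 change of -1.31 ± 0.06 (SE; adjusted p = 2.76e-05). Gja1, which encodes the gap junction protein connexin 43, fell from 103 ± 6.47 to 38.2 ± 1.09 CPM (log2 -1.43 ± 0.06, adjusted p = 2.65e-05). Slpi, a secreted protease inhibitor gene, rose from 46.3 ± 3.85 to 113 ± 3.24 CPM (log2 1.28 ± 0.07, adjusted p = 3.84e-05). Acta2, smooth muscle alpha-actin, rose from 60.6 ± 3.57 to 111 ± 2.27 CPM (log2 0.87 ± 0.06, adjusted p = 1.07e-04). The other genes with the largest increases were Lama2, a laminin chain (1.00), Col8a1 (0.92), Myl9, a regulatory myosin light chain (0.84), and the transporter gene Abca8b (0.74). The other genes with the largest decreases were Rmrp (-2.77), the ribosomal RNA precursor Rn45s (-1.95), Mir6236 (-1.69), Saa3 (-1.57) and Egln3, a prolyl hydroxylase gene (-1.56). Rn45s was at 18761 CPM in siControl 1 and 6287 CPM in siControl 2 against 3041 and 3424 CPM in siH1f0, and Mir6236 at 59.3 and 25.4 CPM against 11.9 and 14.5 CPM. For Rmrp the values were 26.0 and 6.65 CPM against 2.48 and 2.38 CPM. In all, edgeR called 879 of 13427 genes, 305 higher and 574 lower, of which 37 and 140 changed at least 1.5-fold. The libraries did not overlap for 50.6% of genes, against 33.3% by chance. The number of calls was 2882 without siControl 1, 4932 without siControl 2, 336 without siJunb 1, 339 without siJunb 2, 116 without siH1f0 1 and 129 without siH1f0 2. It was 325 with only the 4 libraries compared and 1921 with no filter on low counts. Of 63 called genes named by rule, 16 passed without each of the 6 libraries in turn. In this paragraph Myl9 lost its call without either siH1f0 library (adjusted p up to 0.0721), and Abca8b, Rmrp, Rn45s and Mir6236 without either siH1f0 or either siJunb library (up to 0.170, 0.204, 0.224 and 0.212). Gja1, Egln3, Saa3 and Zmat3 hold in their 3' UTRs a heptamer over-represented among genes lower in siH1f0. Among 505 searched genes lower in siH1f0 39.6% hold one, against 13.5% of matched genes. Of the 85 that were lower at least 1.5-fold, 58.8% hold one, against 13.5% of matched genes. These heptamers too were chosen from the same fold changes, so larger shares among lower genes are no separate evidence. Leaving out all genes that hold one, an alternative chosen after seeing the data, there were 529 calls, 220 higher and 309 lower.

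The p53 response list was lower in siH1f0, with 0 of 19 members up and 8 down (1 and 9 adjusted over the list alone; median -0.16, camera adjusted p = 9.11e-07; adjusted p = 0.145 with an estimated correlation). Besides Zmat3, Ccng1 (-0.66) and Cdkn1a, the gene of the cell cycle inhibitor p21 (-0.49), fell. The NF-kB and inflammation list had 0 of 14 up and 7 down (0 and 9 adjusted over the list alone; median -0.39, camera adjusted p = 9.11e-07; adjusted p = 0.145 with an estimated correlation), including Saa3, Nfkbia, the gene of the NF-kB inhibitor IkB-alpha (-0.45), and Nfkbiz (-0.37). Cholesterol synthesis genes were lower, with 0 of 19 up and 5 down (0 and 11 adjusted over the list alone; median -0.16, camera adjusted p = 3.08e-06; adjusted p = 0.145 with an estimated correlation), including Hmgcs1, HMG-CoA synthase (-0.54), Srebf2, a transcription factor of the pathway (-0.45), Sqle (-0.42) and Msmo1 (-0.35). S phase genes were higher, with 4 of 23 up and 0 down (9 and 1 adjusted over the list alone; median 0.12, camera adjusted p = 6.74e-05; adjusted p = 0.149 with an estimated correlation): Cdc6 (0.32), Rrm1 (0.23), Mcm5 (0.20) and Uhrf1 (0.19). AP-1 target genes were lower, with 1 of 18 up and 7 down (3 and 8 adjusted over the list alone; median -0.11, camera adjusted p = 0.0182; adjusted p = 0.281 with an estimated correlation), including Cxcl1 (-0.80), Hbegf (-0.49), Lif (-0.41) and Cd44 (-0.38), while Dusp1 rose by 0.25. That list lost its call without siControl 1 (adjusted p = 0.105). Calls were lost without either siH1f0 library for Nfkbiz, Cdc6, Cxcl1, Lif and Cd44 (adjusted p up to 0.163), without siH1f0 2 for Hbegf (0.0660), without siH1f0 1 for Nfkbia (0.0907), and for Rrm1 and Mcm5 also without either siJunb library (up to 0.244 and 0.281). Cdkn1a, Nfkbia, Sqle, Cdc6 and Mcm5 hold a 3' UTR heptamer over-represented among genes lower in siH1f0.

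Histone genes were lower in siH1f0 as well. Of 7 linker histone genes, H1f0 included, 0 rose and 3 fell (0 and 5 adjusted over the list alone; median -0.88, camera adjusted p = 2.93e-05; adjusted p = 0.546 with an estimated correlation): H1f0, Hist1h1e (-1.01) and Hist1h1c (-0.85). As H1f0 is the siRNA target, its fall was set by the design, and the list was not tested with camera without it. Without the 2 members that hold a siH1f0 heptamer, H1f0 among them, the median was also -0.88. Of 36 core histone genes 0 rose and 7 fell (0 and 18 adjusted over the list alone; median -1.48, camera adjusted p = 1.92e-10; adjusted p = 0.426 with an estimated correlation), including Hist2h2bb (-1.20), Hist1h2bc (-0.88) and Hist2h2be (-0.60). Core histone counts summed to 25.7 and 25.3 CPM in siH1f0 against 47.3 CPM in siControl 1 and 38.2 CPM in siControl 2, and without siControl 1 the median was -0.93. Hist1h2bc and Hist2h2bb lost their calls without either siH1f0 library (adjusted p up to 0.159 and 0.0760), Hist2h2be also without either siJunb library (0.206), and Hist1h1e without any 1 library but siControl 2 (0.257). Hist2h2be holds a 3' UTR heptamer over-represented among genes lower in siH1f0.

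The other 18 lists tested did not pass in siH1f0 (camera adjusted p from 0.133 to 0.889). Of 21 sarcomere genes 1 rose, Tnni3 (0.68), and 4 fell (3 and 6 adjusted over the list alone): Xirp1 (-1.09), Myoz2 (-0.57), Lmod2 (-0.53) and Cryab (-0.39). Of 12 calcium and conduction genes 0 rose and 3 fell (2 and 4 adjusted over the list alone): Gja1, Jph2 (-0.51) and Casq2 (-0.47). Among 9 cardiac transcription factor genes Hopx rose (0.53) and Mef2d fell (-0.25; 1 and 2 adjusted over the list alone). Of 26 fibroblast and matrix genes 3 rose and 2 fell (7 and 5 adjusted over the list alone): Dcn (0.65), Fbn1 (0.40), Col1a2 (0.34), Loxl1 (-0.35) and Col5a2 (-0.22). Of 19 myofibroblast and TGF-beta genes 2 rose, Acta2 and Myl9, and 1 fell, Ctgf (-0.21; 3 and 4 adjusted over the list alone). Of 13 AP-1 family genes Jdp2 rose (0.22) and Fosl2 (-0.45) and Maff (-0.27) fell (2 and 3 adjusted over the list alone). Counts up and down were 1 and 0 of 23 for G2/M (0 and 0 adjusted over the list alone; Top2a 0.23), 2 and 2 of 18 for senescence-associated secretion (3 and 4; Cxcl12 0.23, Igfbp7 0.28, Ccl2 -0.78 and Cxcl1), 0 and 2 of 38 for interferon-stimulated genes (1 and 2; Gbp2 -0.36 and Xaf1 -0.36) and 0 and 1 of 73 for oxidative phosphorylation (0 and 1; Ndufa4 -0.64). They were 1 and 1 of 17 for the integrated stress response (2 and 1 adjusted over the list alone; Chac1 0.24 and Ddit4 -0.47) and 1 and 0 of 23 for chromatin barriers (1 and 0; Suz12 0.29). For markers of other cell types they were 1 and 1 of 9 for smooth muscle (2 and 1 adjusted over the list alone; Mcam 0.37 and Jph2), 0 and 2 of 6 for neuronal (1 and 2; Tubb3 -0.64 and Ncam1 -0.21), 1 and 0 of 5 for adipocyte (1 and 0; the lipoprotein lipase gene Lpl, 0.63), 0 and 1 of 6 for cartilage and bone (1 and 2; Col11a1 -0.51), and 0 for endothelial and for macrophage and leukocyte genes (5 and 6 measured). The median, the mean or the test differed in sign for myofibroblast, interferon-stimulated, neuronal, adipocyte and chromatin barrier genes. Oxidative phosphorylation passed as higher without siControl 1 (adjusted p = 0.00452), as lower without siControl 2 (8.79e-08) and as lower without siH1f0 2 (0.0186), and sarcomere and G2/M genes passed without siControl 2 (0.0426 each). Of 4 skeletal muscle and 2 pluripotency genes measured, 0 were called. Of the genes in this paragraph Tnni3, Lmod2, Cryab, Jph2, Dcn, Col1a2, Loxl1, Fosl2, Ccl2, Mcam, Tubb3 and Col11a1 lost their calls without either siH1f0 library (adjusted p up to 0.231), and Casq2 without siH1f0 2 (0.0523). Xirp1, Hopx, Mef2d, Fbn1, Ctgf, Jdp2, Maff, Top2a, Cxcl12, Gbp2, Xaf1, Chac1, Ddit4, Suz12 and Ncam1 lost them also without either siJunb library (up to 0.330). Gja1, Fosl2, Mef2d and Col11a1 hold a 3' UTR heptamer over-represented among genes lower in siH1f0.

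The direct comparison sets siH1f0 against siJunb, with the siControl libraries entering its estimate of the spread. Actc1 was at 19.2 ± 1.12 CPM in siH1f0 and 3.90 ± 0.163 CPM in siJunb (SD, n = 2 each), a log2 difference of 2.30 ± 0.10 (SE; adjusted p = 4.42e-06). Tnfrsf19, a receptor of the TNF receptor family, was higher in siH1f0 by 2.11 (77.8 ± 4.52 against 18.0 ± 0.0617 CPM), and Rxfp1 by 1.88. Apart from H1f0 (-3.63), the genes lower in siH1f0 by the most were Saa3 (-2.11, at 2.65 ± 0.127 against 11.4 ± 1.40 CPM), C3 (-2.03) and Lrp4 (-1.87). Junb was higher in siH1f0 by 1.64. edgeR called 3484 of 13427 genes, 1637 higher and 1847 lower in siH1f0, of which 341 and 305 differed at least 1.5-fold. The libraries did not overlap for 71.7% of genes, against 33.3% by chance. The number of calls was 6435 without siControl 1, 6434 without siControl 2, 1311 without siJunb 1, 1325 without siJunb 2, 1304 without siH1f0 1 and 1333 without siH1f0 2, and 6416 with only the 4 libraries compared. Without a scaling factor beyond total counts the calls were 2222 higher and 1340 lower. All 9 called genes named by rule here passed without each of the 6 libraries in turn. Tnfrsf19 and Saa3 hold a 3' UTR heptamer over-represented among genes lower in siJunb, and Saa3 and Lrp4 hold one of those for siH1f0.

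Cell cycle genes were higher in siH1f0 than in siJunb. Of 23 G2/M genes 14 were higher and 1 lower (14 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 2.16e-04; adjusted p = 0.315 with an estimated correlation), among them Mki67 (0.45) and Top2a (0.45), while Aurka was lower (-0.27). Of 23 S phase genes 11 were higher and 1 lower (12 and 2 adjusted over the list alone; median 0.13, camera adjusted p = 2.25e-04; adjusted p = 0.222 with an estimated correlation), with Ccne2 at 0.62, Cdc6 at 0.43 and Ccne1 at -0.20. Of 19 p53 response genes 1 was higher, Sesn1 (0.33), and 13 were lower (3 and 13 adjusted over the list alone; median -0.36, camera adjusted p = 2.64e-06; adjusted p = 0.193 with an estimated correlation). Of 14 NF-kB and inflammation genes 0 were higher and 10 lower (0 and 12 adjusted over the list alone; median -0.49, camera adjusted p = 9.38e-07; adjusted p = 0.193 with an estimated correlation). Of 18 AP-1 target genes 2 were higher, Dusp1 (0.72) and Vegfa (0.27), and 8 lower (2 and 10 adjusted over the list alone; median -0.39, camera adjusted p = 0.0317; adjusted p = 0.316 with an estimated correlation); that call was lost without siControl 1 (adjusted p = 0.0982) or siControl 2 (0.0984). Of 73 oxidative phosphorylation genes 0 were higher and 13 lower (0 and 11 adjusted over the list alone; median -0.09, camera adjusted p = 0.00182; adjusted p = 0.918 with an estimated correlation). The sarcomere list did not pass (camera adjusted p = 0.111), although 8 of its 21 genes were higher and 4 lower (8 and 5 adjusted over the list alone), with Myl7 at 1.77 and Tnni3 at 1.60; it passed without siJunb 2 (0.0481) or siH1f0 1 (0.0297), as did cholesterol synthesis without siJunb 1 (0.0308). The other 18 lists tested did not pass either (camera adjusted p from 0.0826 to 0.972). The median, the mean or the test differed in sign for calcium and conduction, myofibroblast, smooth muscle, adipocyte, and cartilage and bone genes. Mki67, Aurka, Ccne1, Sesn1, Vegfa and the other list members of this paragraph were chosen after their values were seen. Ccne2 and Vegfa hold a 3' UTR heptamer over-represented among genes lower in siJunb, and Cdc6 and Vegfa one of those for siH1f0.

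Calls against siControl were then set side by side. Of the 2209 genes called in siJunb and the 879 called in siH1f0, 55 were higher in both and 87 lower in both, against 26.3 and 44.9 for independent lists of these sizes. Col8a1, Dcn and Acta2 were among the genes higher in both, and Hist1h1c, Lmod2, Casq2 and Hmgcs1 among those lower in both. A further 102 genes were higher in siJunb and lower in siH1f0, such as Zmat3, Ccng1 and Saa3, against 49.5 for independent lists, and 41 were lower in siJunb and higher in siH1f0, such as Tnni3, against 23.9. In 20 simulations of unchanged groups, a mean of 0.35 genes was called in the same direction in both comparisons, at most 2, and 0 in opposite directions. The simulations drew all libraries anew from a common mean and dispersion per gene, with the drawn siControl libraries shared by both comparisons. A departure of siControl 1 as a whole library is not in them, so they may understate the overlap that shared controls produce. Across genes, which are not independent replicates, the log2 changes of the comparisons correlated with Pearson's r = 0.28 and Spearman's rho = 0.19, below the 0.47 and 0.44 of the simulations, and 56.0% of genes had the same sign against 66.2%. Their covariance was 0.0340 against 0.0176 in the simulations, a difference of 0.0165. The 2 siControl libraries could not be divided between the comparisons, and both enter each of them. Without Junb and H1f0 the same-direction count was 141. It was 842 without siControl 1, 2264 without siControl 2, 29 without siJunb 1, 26 without siJunb 2, 15 without siH1f0 1 and 16 without siH1f0 2. The opposite-direction count, 143 in all, was 607 without either siControl library, 20 without siJunb 1, 21 without siJunb 2, 22 without siH1f0 1 and 21 without siH1f0 2. It was 286 with no count filter, 40 with only the 4 libraries compared and 79 with the replicate block.

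**Figure D3:**
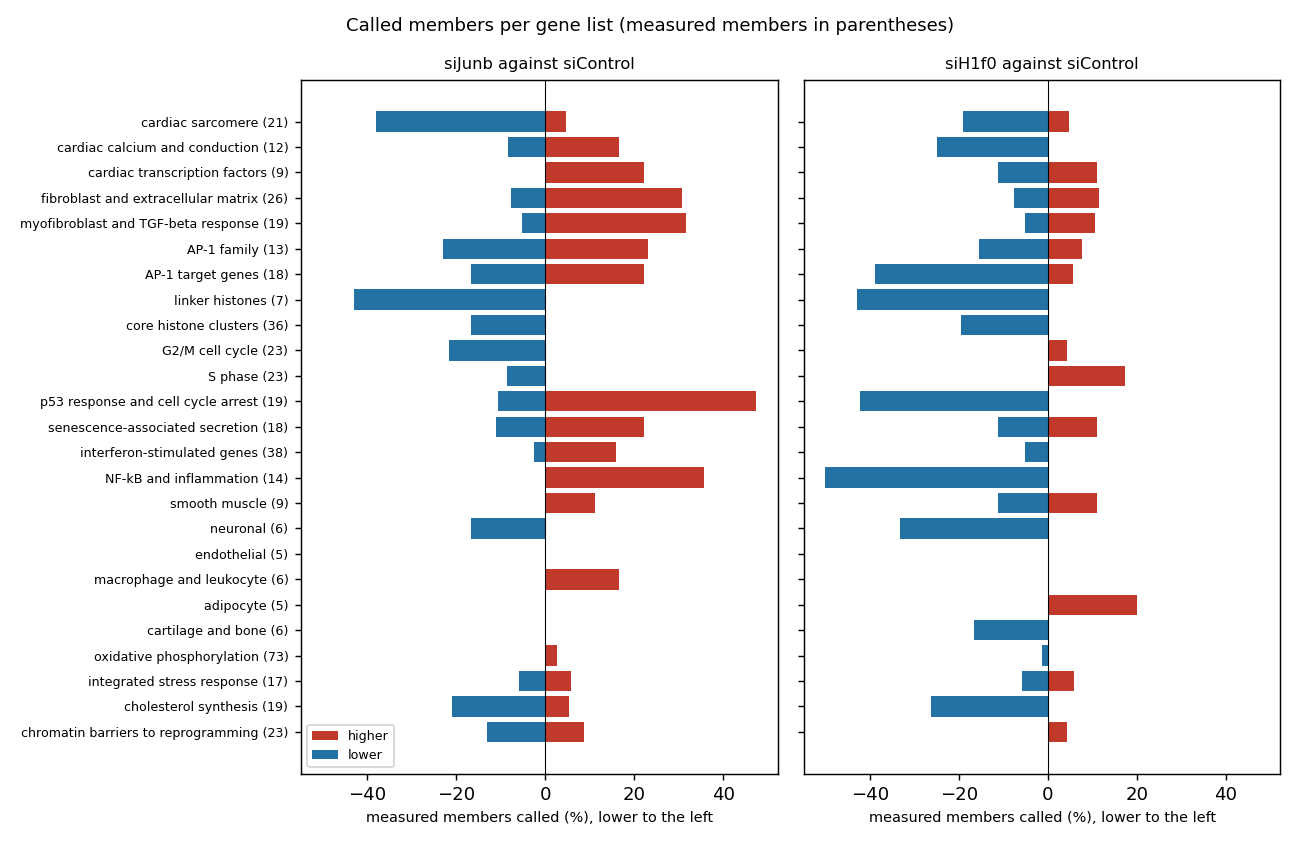
Percent of the measured members of each fixed gene list (y axis, 1 line per list) called higher or lower in siJunb and in siH1f0 against siControl (x axis, percent of measured members), with 1 panel per knockdown and bars to the right for higher and to the left for lower. In the p53 response list 9 of 19 members were higher in siJunb and 8 of 19 lower in siH1f0.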

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

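The tests of the factor levels and of sarcomere genes without a heptamer below were chosen only after the result was seen. Against siControl, 143 genes were called in opposite directions in the knockdowns. This count was 286 with no count filter, 40 with only the 4 libraries compared, 79 with the replicate block, 607 without either siControl library and 20 to 22 without a siJunb or siH1f0 library. A gene called in opposite directions differs in the direct comparison of siH1f0 with siJunb by the sum of both changes, so that comparison gives the size of the difference and no separate evidence for it. Of the genes named here by rule, 19 met this. So did 2 gene lists, the p53 response (median log2 difference -0.36) and NF-kB and inflammation (-0.49), whose direct calls were lost with an estimated correlation (adjusted p = 0.193 for each).

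Genes higher in siJunb and lower in siH1f0 included the inflammation genes Saa3, Cxcl1, Vcam1, Lif and Nfkbiz, with log2 differences of siH1f0 from siJunb of -2.11, -1.47, -1.46, -0.78 and -0.57. The p53-induced genes Zmat3 (-1.79) and Ccng1 (-1.23) and the growth genes Ccnd1 (-1.49) and Hmga2 (-1.21) moved the same way. So did Lrp4 (-1.87), Mef2d (-0.72), Fosl2 (-0.68) and Col5a2 (-0.50). Genes lower in siJunb and higher in siH1f0 included Tnfrsf19 (2.11), the muscle gene Tnni3 (1.60), Lama2 (1.49), Dusp1 (0.72), Suz12 (0.51) and Top2a (0.45). Ccng1, Lif, Saa3, Suz12, Tnfrsf19 and Vcam1 hold a 3' UTR heptamer over-represented among genes lower in siJunb. Fosl2, Lrp4, Mef2d, Saa3 and Zmat3 hold one of those for siH1f0.

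The sarcomere list was lower in siJunb than in siControl (camera adjusted p = 2.78e-04; adjusted p = 0.553 with an estimated correlation), while in the direct comparison with siH1f0 it did not pass (adjusted p = 0.111), with 8 of 21 members higher in siH1f0 and 4 lower. Less of the induced factors in siJunb is argued against, since the mean of Mef2c, Gata4 and Tbx5 in siJunb was 95.3% of that in siH1f0. Direct 3' UTR seed matches are argued against as the whole cause, since the 17 members without a siJunb heptamer kept the list's median (-0.36) and its call (camera adjusted p = 8.01e-04; adjusted p = 0.553 with an estimated correlation). For Ldb3 and Myoz2, 25.0% of the 8 members that fell against 9.88% of matched genes, seed matches cannot be told apart from an effect of losing Junb, as 2 genes are too few. The sarcomere members were not searched outside the 3' UTR. Over all scanned genes AGCAGTT, GCGGAAC and GAGCGCT in coding sequences also went with lower values in siJunb (z -7.49, -7.46 and -5.17). Direct matches outside the 3' UTR, effects of the siRNA through other genes and a need for Junb all stay open. A rescue with Junb or siRNAs of other sequence, not analysed here, would test them.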

How the results depend on the processing

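The count without genes that hold a chosen heptamer was chosen only after the result was seen. With each library left out in turn, Junb fell in siJunb (log2 -2.07 to -1.81) and H1f0 in siH1f0 (-3.92 to -3.81), both past the test. Counts of calls and their overlap stayed within 1.5 times under RLE factors, total counts only, a mean of at least 5 CPM, DESeq2 and limma-voom. Without a filter, which raised the genes tested from 13427 to 17713, siH1f0 had 1921 calls and the overlap was 460. With only the 4 libraries compared, calls were 1094 for siJunb, 325 for siH1f0 and 6416 for the direct comparison, and the overlap was 38. With the replicate number as a block, siH1f0 had 550 calls and the overlap was 82, although the numbers do not pair the libraries (correlations of deviations 0.0477, -0.0412 and 0.0627). With a library left out, calls ran from 352 to 5521, from 116 to 4932 and from 1304 to 6435, and the overlap from 15 to 2264. For these the cause was not tested. Without genes that hold a heptamer siH1f0 had 529 calls among the 11919 genes left. Its higher calls fell from 305 to 220, although only 22 of 273 searched higher genes hold a heptamer. Leaving those genes out does not account for the whole fall. The p-values of the main fit were kept and only adjusted again over the genes left. Higher genes without a heptamer could therefore lose their calls only through that adjustment. With an estimated correlation, under which camera also tests on 3 residual degrees of freedom, 0, 0 and 0 lists were called, and fry called 15 in the direct comparison. Signs turned without siControl 1 for Gata4 (siJunb, -0.0449, range up to 0.688) and Tbx5 (siJunb, -0.0841, up to 0.366; siH1f0, -0.00114, up to 0.452). They turned without siH1f0 1 for Mef2c (direct, -0.0503, up to 0.101) and without siControl 2 for the oxidative phosphorylation list (siJunb, -0.0256, up to 0.148), and the cause was not tested. Of 148 values of named genes, 7 were stronger with no count filter (Junb in siH1f0 and the induced factors against siControl), 37 were weaker and 2 stronger with only 4 libraries, 14 weaker with the block, and 55 to 59 weaker without a siJunb or siH1f0 library. Of these values, 3 were weaker and 1 stronger with DESeq2, 4 weaker with limma-voom and 3 weaker with total counts only. With a mean of at least 5 CPM, 1 of 135 was weaker. Rmrp in siJunb lost its call with DESeq2 (adjusted p = 0.0951), limma-voom (0.165) and a mean of at least 5 CPM (0.0563). In siH1f0 Hist1h1e, Mir6236 and Rmrp lost theirs with limma-voom (adjusted p = 0.0617, 0.0515 and 0.125). Of 15 list calls against siControl, fry lost 4 and the replicate block lost 1. Depth limits genes near the floor such as the core histones (median 0.215 CPM).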

Other observations

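The tests of base composition and of noise below were chosen only after the result was seen. Some list members outside the naming rule, chosen after their values were seen, changed as well. Igfbp5, which encodes a secreted IGF-binding protein, fell from 0.890 ± 0.266 CPM in siControl to 0.263 ± 0.101 CPM in siJunb (SD, n = 2 each; log2 -1.77, edgeR adjusted p = 0.0175). It was at 1.13 ± 0.184 CPM in siH1f0, a log2 difference of 0.36 that did not pass (adjusted p = 0.519). Col6a3, a collagen VI chain, rose in siJunb from 1.13 ± 0.0814 to 2.31 ± 0.190 CPM (log2 1.04, adjusted p = 0.0113). Eda2r, a p53-induced receptor gene, fell in siH1f0 from 87.9 ± 19.9 to 45.5 ± 0.656 CPM (log2 -0.95, adjusted p = 0.00362). Phlda3, another p53 target, rose by 0.34 in siJunb (adjusted p = 0.0193) and fell by 0.62 in siH1f0 (adjusted p = 0.00274). Libraries were not left out in turn for these genes.

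Genes lower in a knockdown shared 3' UTR heptamers, AGCAGTT (z -13.0), GCGGAAC (-7.85) and GAGCGCT (-7.43) for siJunb and GTGGACT (-19.4) and GCGTCCT (-12.6) for siH1f0, against a lowest z of -3.47 with permuted fold changes. Noise of 1 set of libraries is argued against, since the heptamers chosen in replicate 1 had z of -7.07 or lower in replicate 2. Base composition is argued against for 4 of them, where rearranged heptamers reached at most 43.4% of the z, and stays open for GAGCGCT (57.0%). A candidate explanation is siRNA seed matches, since the Junb mRNA holds 3 of 3 siJunb heptamers and the H1f0 mRNA 2 of 2 siH1f0 heptamers, while at most 1.84% of mRNAs of like length hold as many. As the siRNA sequences were not available here, this stays a hypothesis, under which part of the genes lower in each knockdown may respond to the siRNA itself.

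Core histone genes were lower in both knockdowns (median log2 -1.12 in siJunb and -1.48 in siH1f0), and 30 of 36 were higher in siControl 1 than in siControl 2. Rn45s (18761 against 6287 CPM), Rmrp (26.0 against 6.65 CPM) and Rpph1 (15.7 against 3.95 CPM), RNAs without poly(A) tails, were also higher in siControl 1. An excess of such RNA in siControl 1 cannot be told apart from an effect of the knockdowns, since without that library the medians kept 46.4% and 63.0% of their size and 1 siControl library is left. Against siControl 2 alone, 25 of 36 genes were lower in both siJunb libraries and 32 of 36 in both siH1f0 libraries. However, siControl 2 also lay above both siH1f0 libraries for Rn45s (3041 and 3424 CPM), Rmrp (2.48 and 2.38 CPM) and Rpph1 (0.997 and 1.36 CPM). It lay above both siJunb libraries for Rmrp (5.80 and 3.35 CPM) and Rpph1 (3.07 and 2.24 CPM), but not for Rn45s (6685 and 5082 CPM). The comparison with siControl 2 therefore does not remove this explanation. An effect of either knockdown on histone genes stays open as a biological explanation.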
